A study of Mus musculus with 8 samples.

How the data were processed

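The series holds 8 Affymetrix whole-transcript arrays of mouse splenic cDC1 (type 1 conventional dendritic cells, the subset specialised in presenting antigen to CD8 T cells) from naive wild-type C57BL/6 mice. Per the labels, cells were sorted into a TMRM/MG-high and a TMRM/MG-low fraction, with 4 arrays of each. TMRM is a dye that collects in mitochondria with their membrane potential. The labels do not spell out MG. Replicates 1 to 4 carry the same numbers in both groups, and no label says whether a number marks an animal, a pool or a sorting day, so p-values measure only the spread between these samples, which may be technical. A cDC2 sort that the labels mention was not analysed here.

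The values used are the deposited log2 signals. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console 1.1, and per the labels biotin-labelled target came from the Whole Transcript Plus kit after column extraction of total RNA. RMA corrects the background, gives the probes of all arrays one distribution and summarises them per probe set, so a shift shared by most transcripts is removed before deposit, and differences are relative to the other probe sets. The genome build is not given in the sources used here, so no coordinates are printed. Scanner files and detection calls were not used here, and the number of arrays limits the precision. Exon controls ranked above intron controls with an area under the curve of 0.918 in the high and 0.912 in the low arrays. Figures were drawn with matplotlib 3.10.9.

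Of 28846 deposited rows, 6640 control probe sets were left out of the comparison: 5222 negative (intron) controls, 1324 positive (exon) controls, 63 ERCC, 23 background and 8 spike-in probe sets. The spike-ins are 4 poly-A RNAs added to the sample and 4 hybridization controls added to the labelled target. Of the 22206 probe sets tested, 19572 had 1 gene symbol in the platform annotation, 2634 were unnamed and none had several. All 19572 matched the RefSeq gene table (assembly GRCm38.p6) by Entrez ID, and no symbol changed. They stand for 19505 genes. Near-identical family members (Ly6c2, Klra17, Cd209d, Nlrp1b, Hspa1b, olfactory receptors) may share probes, and their values are uncertain to that extent.

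TMRM/MG-high was compared with TMRM/MG-low by lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, two-sided, with Benjamini-Hochberg adjustment over the 22206 probe sets and a threshold of 0.05. Differences are log2, high minus low, with the moderated standard error (SE). Of 38 gene lists fixed before the data were examined, 36 had 5 or more measured genes. These and the union of the 3 respiratory chain lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 sets, and again with an estimated correlation. Genes with several probe sets entered with the one of highest mean. List levels per array were compared by two-sided exact permutation tests of the 4 against 4 arrays, for which the smallest possible p is 0.0286. The same procedure was tested on simulated data: 200 of 22206 probe sets were changed, of which 48% of those changed by 0.5 and 97% of those changed by 1 on the log2 scale were recovered, with 8 false calls among 153. The simulated noise was independent between probe sets and held no trend shared by an array, so these rates need not hold for the real arrays.

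Named genes followed a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called, named probe sets whose groups did not overlap (symbols of the Gm-number, Rik, Mir, Snor and LOC kinds left out), up to 4 called members of each list with the smallest p (up to 2 where none was called), and Xcr1, Clec9a, Irf8, Batf3, Cd8a, Sirpa, Irf4, Opa1, Nrf1, Tfam, Abcb1a, Abcb1b and Abcg2. A few other genes are named beside small counts and were chosen after their values were seen.

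Alternatives fixed before the data were examined were the replicate number as a block, quantile normalization again over the tested probe sets, centring on array medians, leaving out dim probe sets, an intensity trend with a robust fit, array weights, other thresholds, 1 row per gene, an unmoderated test with unequal variances, the mean of a gene's probe sets, an estimated correlation, and leaving out each array. The mean spike-in level as a covariate was added after seeing the data. One further run, without the 2 arrays nearest the other group on the first principal component, was made and discarded, because it picked arrays by the outcome.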

Results

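Gene expression was measured in splenic cDC1 of naive mice sorted by a mitochondrial dye signal, with 4 arrays of the TMRM/MG-high and 4 of the TMRM/MG-low fraction. The design asks how the transcriptomes of the fractions differ. Arrays of one fraction correlated at r = 0.992 to 0.994 (high) and 0.990 to 0.992 (low) across probe sets, against 0.982 to 0.992 between fractions. The first principal component (41.3% of the variance) separated the fractions, from -26.7 to -2.97 for the low and from 5.55 to 23.5 for the high arrays. Median signal was 8.11 to 8.16 on every array.

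In TMRM/MG-high cDC1, genes associated with plasmacytoid dendritic cells, nuclear-encoded mitochondrial genes, cholesterol synthesis genes and cell cycle genes were higher, and T and NK cell genes were lower, by a set test with a preset correlation between genes. None of these list calls held with an estimated correlation (adjusted p = 0.283 for the plasmacytoid and cholesterol synthesis lists and 0.41 for the others), and with the spike-in level as a covariate the respiratory chain, cell cycle and T and NK cell calls were lost. The largest named rises were Cd209d (log2 difference 1.83, SE 0.21, limma adjusted p = 0.0012), Havcr1 (1.82, SE 0.25), Siglech (1.81, SE 0.17) and Klk1 (1.52, SE 0.13). The largest named falls were Nlrp1b, an inflammasome sensor (-1.27, SE 0.11, adjusted p = 0.00042), Leng8 (-1.18, SE 0.14) and Rsrp1 (-1.09, SE 0.097). Further rises were Olfr164 (1.33), Tex30 (1.26), Lrp8 (1.17), Klra17 (1.14), Gapt (1.1), Epha2 (1.04), Sccpdh (1.02) and Atp1b1 (0.98). Further falls were Gimap3 (-1.08), Ppm1m (-1.06), Fam193b (-1.04), the RNA-binding protein gene Hnrnpm (-1.04), Zfp101 (-1.04), Rhobtb1 (-1.02), Ppef2 (-1.01), Zfp687 (-0.97) and Tcirg1 (-0.96). The negative controls had a median of 6.76 in the low and 6.86 in the high arrays, and the mean of Havcr1 (6.57), Olfr164 (6.23) and Sccpdh (6.08) in the low fraction and of Zfp101 (6.78) in the high fraction lay below it, so the size and rank of these differences are uncertain.

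In all, 1173 probe sets were higher and 658 lower (8.25% of those tested), of which 202 and 145 differed by at least 1.5-fold. Median differences among the calls were 0.44 and -0.44, and the highest, of an unnamed probe set, was 1.95. The 4 high arrays did not overlap the 4 low arrays in 16.1% of all probe sets tested, against 2.86% by chance, and in 92.2% of the calls, which the test selects for such separation. The split depended on scaling: quantile normalization of the tested probe sets gave 852 higher and 858 lower (49.8% higher, against 64.1%). Counts moved on leaving out 1 array: they were 367 and 305 without low replicate 1, 437 and 297 without low replicate 2, 499 and 386 without low replicate 4, 183 and 242 without high replicate 2, 255 and 218 without high replicate 3, and 395 and 360 without high replicate 4. They rose to 1680 and 793 without low replicate 3, and to 1356 and 698 without high replicate 1. A smaller group also gives the test less power, so a fall alone does not single out an array. Of the 108 named genes called, 47 kept their call in all 8 omissions, among them all those named so far except Tex30, Gapt and Gimap3. The others that kept it were Ndufa9, Mrpl41, Mrpl13, Idh2, Idh3a, Tfb1m, Pprc1, Mcu, Nampt, Gpd2, Hadhb, Ebp, Pmvk, Fdps, Ctsl, Ciita, Il15, Bst2, Stat2, Pclaf, Atg7, Jund, Itga8, Ly6c2, Cd3e and Csf3r, and the other 61 lost it without at least 1 array. After quantile normalization 93 kept it, and Uqcrc1, Cox5a, Fis1, Slc25a4, Slc25a12, Aldoc, Canx, Cd83, Cxcl10, Ddx21, Dnajb9, Hsp90b1, Prdx1, Atp6v1h and Cd36 lost it.

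**Figure D1:**
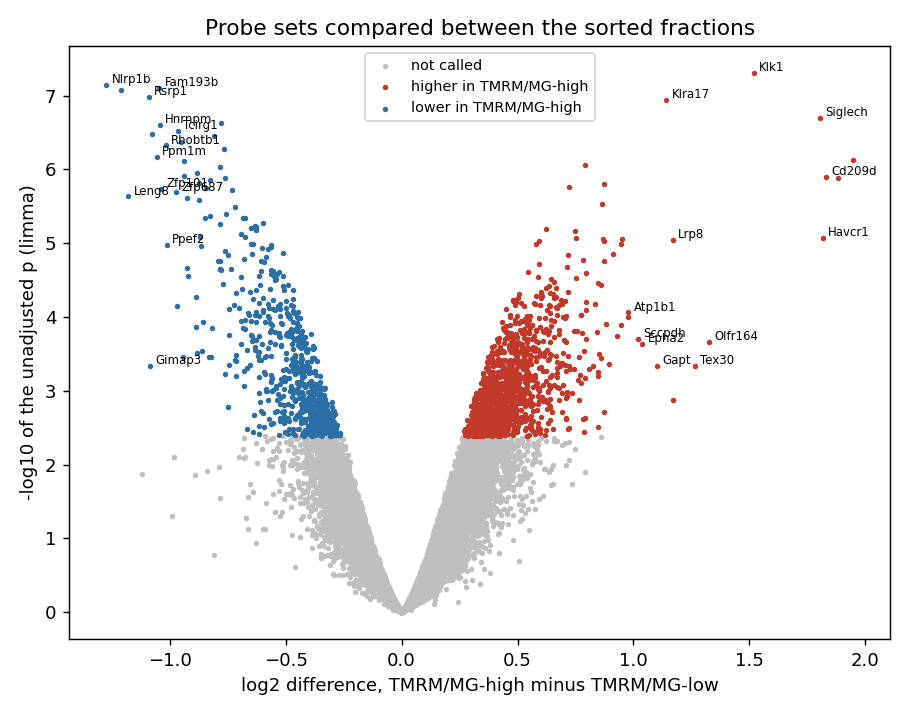
Log2 difference (x axis, TMRM/MG-high minus TMRM/MG-low) against -log10 of limma's unadjusted p (y axis), 1 point per probe set, with the called rises and falls coloured and the 12 largest named of each labelled. The 1173 calls on the right outnumber the 658 on the left, and Siglech (1.81) and Cd209d (1.83) lie far to the right.

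Control probe sets also separated the fractions and are given here because every comparison below is between the same fractions. The poly-A spike-in dap was 7.26 ± 0.81 in the high and 9.50 ± 0.49 in the low arrays (SD, n = 4 each; difference -2.25), and thr differed by -1.56. The hybridization control bioB was 10.1 ± 0.14 against 11.1 ± 0.24, and GC-rich background probe sets were 8.78 ± 0.028 against 9.31 ± 0.12. Exon controls were higher in the high arrays, by 0.16. Each of these had no overlap of the groups (exact p = 0.0286, the smallest possible, adjusted 0.0508 over 16 measures). The poly-A spike-ins phe (-0.64, exact p = 0.0857) and lys (-0.46, exact p = 0.0571) differed less and overlapped between the fractions. Both had means below the negative control median in each fraction, so the size of their differences is uncertain. The high mean of thr (6.57) also lay below that median (6.86 in the high arrays), as did dap in high replicates 3 (6.52) and 4 (6.80). The sizes of the thr and dap differences are uncertain to that extent. With the mean spike-in level as a covariate, chosen after seeing the data, limma called 0 probe sets in either direction, and 472 and 568 had an unadjusted p under 0.05.

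**Figure D2:**
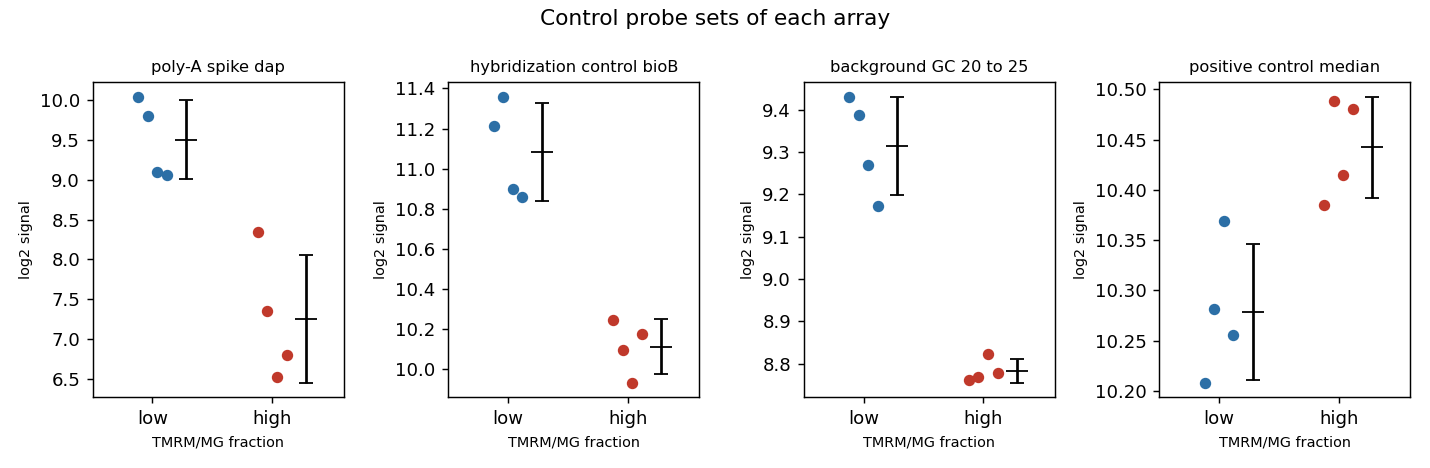
Log2 signal (y axis) of 4 kinds of control probe set on each array of the TMRM/MG-low and TMRM/MG-high fractions (points, with mean and SD at the side). All 4 high arrays lie below all 4 low arrays for dap, bioB and the GC-rich background, and above them for the exon controls.

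Genes of the respiratory chain, whose complexes build the membrane potential that TMRM follows and use it to make ATP, were higher in TMRM/MG-high cells. Of 76 measured, 27 rose and 0 fell (limma, over all probe sets; 48 rose and 1 fell adjusted over the list alone), and their mean difference was 0.26 (camera adjusted p = 1.39e-15, and adjusted p = 0.41 with an estimated correlation). Complex I had 15 of 35 rising (28 and 1 fall adjusted over the list alone), as in Ndufa9 (0.49, SE 0.087, adjusted p = 0.0112) and Ndufb9 (0.49). Complexes II to IV had 7 of 25 (12 over the list alone), including Uqcrfs1 (0.48) and Cox5a (0.28), and ATP synthase 5 of 16 (10 over the list alone), including Atp5o (0.55) and Atp5g3 (0.39). Mean differences were 0.31, 0.21 and 0.25, with camera adjusted p = 6.97e-12, 3e-06 and 2.84e-05, each with adjusted p = 0.41 under an estimated correlation. The mean level of the 76 genes was 11.5 ± 0.074 in the high and 11.2 ± 0.098 in the low arrays (SD, n = 4; exact p = 0.0286, adjusted 0.0756 over 37 sets). With the spike-in covariate the difference was 0.043 and not called. No gene of the mitochondrial genome was named on the array annotation used, so that list is not analysed here.

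The lists of the mitochondrial ribosome, TCA cycle, fatty acid oxidation, membrane potential carriers, and mitochondrial dynamics and mitophagy were also called higher at the preset correlation, and each had adjusted p = 0.41 with an estimated correlation. None of the 5 was compared with random lists matched on expression and gene length. Genes of the mitochondrial ribosome had 18 rises and 1 fall among 74 (32 and 1 over the list alone), with Mrpl13 at 0.78 (SE 0.14), Mrpl41 at 0.47 and the fall in Mrps22 (-0.47), a mean of 0.25 and camera adjusted p = 3.12e-10 (adjusted p = 0.41 with an estimated correlation). The levels of this list overlapped between the fractions (low replicate 3 at 9.681, high replicate 1 at 9.676; exact p = 0.0571, adjusted 0.106). In the TCA cycle 6 of 20 rose (8 and 1 fall over the list alone), including Idh3a (0.84, SE 0.16), Dlat (0.69) and Idh2 (0.47), with a mean of 0.20 and adjusted p = 0.00406 (0.41 with an estimated correlation). Fatty acid oxidation had 5 of 16 rising (7 over the list alone), such as Etfdh (0.64), Hadhb (0.50) and Slc25a20 (0.53), mean 0.24, adjusted p = 0.000505 (0.41 with an estimated correlation). Membrane potential carriers had 2 of 10 (3 over the list alone): Mcu, the mitochondrial calcium uniporter (0.71, SE 0.12), and the ADP/ATP carrier Slc25a4 (0.30), with a mean of 0.24 and adjusted p = 0.00192 (0.41 with an estimated correlation). Mitochondrial dynamics and mitophagy had 2 of 22 (3 over the list alone), the fission genes Dnm1l (0.40) and Fis1 (0.28), with a mean of 0.17 and adjusted p = 0.00355; this call was lost when dim probe sets were left out (adjusted p = 0.0854). With the spike-in covariate none of the 5 lists was called and the mitochondrial ribosome (-0.017) and TCA cycle (-0.017) turned negative.

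Regulators of mitochondrial biogenesis, which control transcription of nuclear and mitochondrial genes for the organelle, went both ways. Of 18 measured, Tfb1m (0.58, SE 0.080), Gabpa (0.39) and Ssbp1 rose, and Pprc1 (-0.62, SE 0.12) and Nrf1 (-0.36, SE 0.095) fell (3 and 2 also over the list alone). The list was not called (mean 0.11, camera adjusted p = 0.219). Tfam, the mitochondrial transcription factor, differed by 0.16 (SE 0.13, adjusted p = 0.506) and Opa1, a fusion gene, by 0.15 (SE 0.094, adjusted p = 0.333). The Nrf1 call was lost without any one of the 8 arrays (highest adjusted p = 0.099). NAD metabolism and shuttles had 3 rises and 1 fall among 19 (5 and 2 over the list alone): Nampt (0.69, SE 0.11), Slc25a13 (0.39) and Slc25a12 (0.36) rose and Gpd2 (-0.58, SE 0.097) fell. Glycolysis had 3 and 1 among 19 (5 and 1 over the list alone), with Hk1 at 1.17 (SE 0.28), Tpi1 at 0.44, Aldoc at 0.43 and the lactate exporter Slc16a3 at -0.59; the low mean of Hk1 (5.99) lay below the negative control median (6.76), so its size is uncertain. Neither list was called (means 0.086 and 0.16, adjusted p = 0.291 and 0.0908); glycolysis was called without low replicate 2 (adjusted p = 0.0491) or high replicate 3 (0.0396).

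Cholesterol synthesis genes, which are under control of the SREBP transcription factors, were higher: 6 of 19 rose (12 over the list alone), as in Ebp, a sterol isomerase (0.95, SE 0.13, adjusted p = 0.0035), Pmvk (0.61), Fdps (0.53) and Insig1 (0.37). The mean was 0.30 (camera adjusted p = 3e-05), and with an estimated correlation the unadjusted p was 0.0153 and the adjusted p = 0.283. With the spike-in covariate camera still called it (mean 0.25, adjusted p = 0.00913), but the 95% interval of the list level was -0.048 to 0.55, which includes 0. Cholesterol efflux genes were not called (0 of 8, also over the list alone; mean 0.089, adjusted p = 0.531), with Abca1, a cholesterol exporter, at 0.40 (SE 0.13; called without high replicate 1, 0.50) and Abcg1 at -0.19 (SE 0.087).

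Cell cycle genes were higher: 13 of 40 rose and 0 fell (24 over the list alone). Pclaf, a DNA replication factor, differed by 0.62 (SE 0.099, adjusted p = 0.0074), Cdc20 by 0.54, Kif23 by 0.44 and Ccnb2 by 0.38. The mean was 0.29 (camera adjusted p = 7.55e-10), and with an estimated correlation the unadjusted p was 0.0373 and the adjusted p = 0.41. With the spike-in covariate the mean was 0.090 and not called. Ribosome biogenesis and MYC targets had 1 rise (Ddx21, 0.32) and 1 fall (Myc itself, -0.37) among 29 (6 and 1 over the list alone), with a mean of 0.13 and adjusted p = 0.0103 (adjusted p = 0.41 with an estimated correlation). Cytosolic ribosome genes had 0 of 47 called (0 over the list alone; mean 0.064, adjusted p = 0.0957), with Rpl11 at 0.23 and Rps21 at 0.22; the list was called without high replicate 1 (0.085, adjusted p = 0.0218) and with an intensity trend and robust fit (0.00153). MYC targets were not called after quantile normalization (adjusted p = 0.181), with dim probe sets left out (0.175), without low replicate 4 (0.051) or with the spike-in covariate (0.584).

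Plasmacytoid dendritic cells are a related lineage that makes type I interferon, and their marker genes had the largest difference of the 37 sets. Of 13 measured, 11 rose and 0 fell (12 over the list alone): Siglech, Klk1 and Cd209d (above), Bst2 (0.79, SE 0.086), Atp1b1, Ccr9 (0.94), Ly6c2 (0.85), Lair1 (0.85), Ly6d (0.55), Tcf4 (0.40) and Pacsin1 (0.38). Cox6a2 (0.20, adjusted p = 0.144) and Spib (0.19, adjusted p = 0.276) did not pass. The mean was 0.87 (10.2 ± 0.19 high and 9.32 ± 0.075 low, SD, n = 4), camera adjusted p = 1.51e-12, and adjusted p = 0.283 with an estimated correlation (unadjusted 0.0116). Siglech and Ly6c2 are also in the list of DC precursors, where with Zbtb10 (0.58) they made 3 rises among 15 (4 over the list alone); that list was not called (mean 0.15, median -0.047, adjusted p = 0.513). With the spike-in covariate the plasmacytoid list stayed called (mean 0.77, adjusted p = 7.67e-09).

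cDC1 identity genes, which include the chemokine receptor Xcr1, the dead-cell receptor Clec9a and the lineage factors Irf8 and Batf3, were not shifted as a list (mean -0.0023, median 0.13, camera adjusted p = 0.913). Xcr1 differed by 0.14 (SE 0.083), Clec9a by -0.21 (SE 0.075), Irf8 by -0.17 (SE 0.083), Batf3 by 0.20 (SE 0.098) and Cd8a by 0.31 (SE 0.094, adjusted p = 0.0639), none called; Cd8a was called without low replicate 3 or without high replicate 1 (0.36). Of 23 measured, Itga8 (-0.94, SE 0.11) and Fnbp1 (-0.29) fell and Cd36 (0.37) rose (3 falls and 2 rises over the list alone). cDC2 identity genes had 1 rise (Ccr2, 0.51) and 2 falls (Tbx21, -0.88, SE 0.18, and Notch2, -0.33) among 19 (2 and 2 over the list alone; mean -0.040, adjusted p = 0.535). The cDC2 list was called lower without high replicate 4 (-0.15, adjusted p = 0.0322). Sirpa (0.091) and Irf4 (0.15) were not called.

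Antigen presentation, costimulation and cytokine genes carry the function of dendritic cells, and few of them passed the test. In MHC class I presentation 1 of 23 rose (0 over the list alone), Canx (0.34), with a mean of 0.13 and camera adjusted p = 0.00969; the call was lost after quantile normalization (0.163), with dim probe sets left out (0.115), without low replicate 1 (0.05), with the spike-in covariate (0.972) and with an estimated correlation (adjusted p = 0.549). MHC class II presentation had 1 rise, Ctsl (0.87, SE 0.11), and 1 fall, Ciita (-0.60, SE 0.087), among 14 (1 and 1 over the list alone; mean 0.078, adjusted p = 0.291). DC maturation genes had 3 rises among 28 (3 over the list alone): Il15 (0.63, SE 0.12), Ccl22 (0.60) and Cd83 (0.29). The Cd83 call was lost on leaving out any 1 of the 8 arrays (highest limma adjusted p = 0.123). The mean was 0.099 and the list was not called (adjusted p = 0.0957); it was called without low replicate 2 (0.15, adjusted p = 0.00595), without high replicate 3 (0.12, adjusted p = 0.0379) and with the spike-in covariate (0.21, adjusted p = 0.0124). Inflammatory cytokines had 1 rise among 21, Cxcl10 (0.32; 0 over the list alone; mean 0.097, adjusted p = 0.18). Interferon-stimulated genes had 2 rises (Bst2, Cxcl10) and 1 fall (Stat2, -0.54) among 30 (2 and 1 over the list alone; mean -0.0049, adjusted p = 0.535).

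Lists of stress responses, and of genes induced by tissue handling, were measured too. The antioxidant response had 2 rises, Gclm (0.67, SE 0.14) and Prdx1 (0.35), among 19 (7 over the list alone; mean 0.13, camera adjusted p = 0.018). This call was lost after quantile normalization (0.0707), with dim probe sets left out (0.191), without low replicate 4 (0.061) or high replicate 4 (0.0559), with the spike-in covariate (0.866) and with an estimated correlation (adjusted p = 0.41). The integrated stress response had 3 of 23 (Psat1 0.53, Dnajb9 0.34, Hsp90b1 0.32; 3 over the list alone; mean 0.050, adjusted p = 0.423). Lysosome and autophagy had 3 rises (Gabarapl1 0.49, Atp6v1h 0.37, Mitf 0.33) and 1 fall (Atg7, -0.66, SE 0.11) among 25 (3 and 2 over the list alone; mean 0.082, adjusted p = 0.117). Apoptosis and p53 targets had 0 of 22 (0 over the list alone; mean 0.087, adjusted p = 0.297), with Cdkn1a at 0.30 and Mdm2 at 0.45 (called without high replicate 1, 0.58). Immediate early and dissociation genes had 0 rises and 3 falls among 27 (4 falls over the list alone), Jund (-0.68, SE 0.099), Jun (-0.40) and Hspa1b (-0.57), with a mean of -0.067, a median of 0.0049 and adjusted p = 0.179; after quantile normalization it was called (-0.13, adjusted p = 0.0208). Dye efflux pumps had 0 of 10 (0 over the list alone; mean 0.094, adjusted p = 0.425): Abcb10 differed by 0.33 (called without low replicate 3, 0.47), Abcc1 by 0.18, Abcb1a by 0.10, Abcb1b by 0.25 and Abcg2 by 0.11 (both means below the negative control median). Only 3 sex-linked genes were measured and none was called (Uty 0.14, Eif2s3y -0.031, both with means below the negative control median).

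Marker genes of other spleen cells were measured too. T and NK cell genes had 4 falls and 1 rise among 19 (12 and 1 over the list alone): Cd3e (-0.86, SE 0.15), Cd3d (-0.82), Cd3g (-0.76) and Bcl11b fell, and Klrk1 (0.54, SE 0.13) rose. The mean was -0.46 (8.92 ± 0.24 high and 9.38 ± 0.35 low, SD, n = 4; exact p = 0.0857, adjusted 0.127), camera adjusted p = 4.61e-06, and adjusted p = 0.41 with an estimated correlation; with the spike-in covariate it was -0.14 and not called. Monocyte and neutrophil genes had 1 fall, Csf3r (-0.81, SE 0.080), and 2 rises, Ly6c2 and Ccr2, among 20 (7 falls and 2 rises over the list alone; mean -0.38, adjusted p = 0.000978, and adjusted p = 0.41 with an estimated correlation). The mean was -0.25 without high replicate 4, and list levels per array gave exact p = 0.171 (adjusted 0.218). B cell genes had 0 of 13 (0 over the list alone; mean 0.018, median -0.019, adjusted p = 0.925), with Fcrla at 0.14 and Jchain at 0.22. Macrophage genes had 0 of 19 (0 over the list alone; mean 0.11, adjusted p = 0.291), with Fcna at 0.31 and Lyz2 at -0.17. Without high replicate 1 the list (0.19, adjusted p = 0.0179) and Fcna (0.44) were called, and without high replicate 4 the list mean was 0.029. Erythroid and platelet genes had 0 of 9 (0 over the list alone; mean -0.056, median 0.0041, adjusted p = 0.614), with Rhag at -0.51 (both means below the negative control median) and Alas2 at -0.34.

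In all, 15 of the 37 sets were called higher and 2 lower at the preset correlation. With an estimated correlation 0 were called (lowest adjusted p = 0.283), and 3 had an unadjusted p under 0.05. Random lists matched to the respiratory chain genes on expression and gene length had a median difference of 0.10, against 0.0093 for all probe sets tested. Called means near that, as for MHC class I presentation, MYC targets and the antioxidant response (0.13 each), may go with expression or length. Only the respiratory chain was compared with matched lists. Chance is not excluded for the number of sets called, since 9 of the 35 splits of the arrays into 4 and 4, the real one included, gave at least 17. The direction of the integrated stress response (-0.0022) and B cell (-0.040) lists turned after quantile normalization. With the spike-in covariate 10 sets were called at the preset correlation, and an estimated correlation was not tried with the covariate. Of these 10, macrophages (-0.41, adjusted p = 5.27e-07) and cholesterol efflux (-0.30, adjusted p = 0.0109) had turned negative. Interferon-stimulated genes (-0.30), cDC1 identity (-0.15), immediate early genes (-0.17), inflammatory cytokines (0.24) and DC maturation (0.21) were newly called. The plasmacytoid, cholesterol synthesis, and monocyte and neutrophil (-0.42, adjusted p = 0.0164) lists kept their calls.

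**Figure D3:**
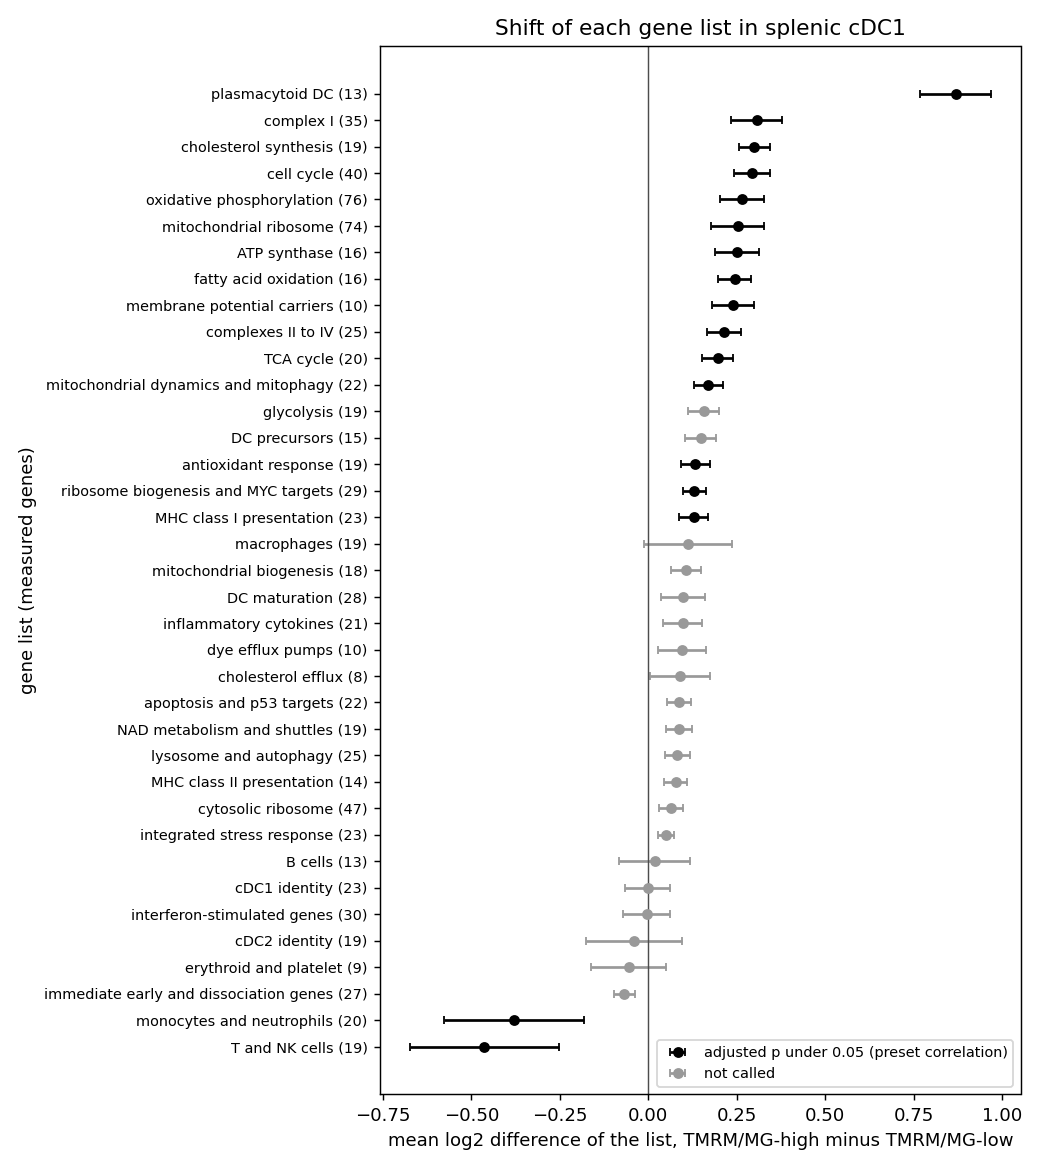
Mean log2 difference of each tested list (x axis, TMRM/MG-high minus TMRM/MG-low; measured genes in parentheses), with the standard error from the spread of list levels between the 4 + 4 arrays, and lists called at the preset correlation in black. The plasmacytoid list lies at 0.87, complex I at 0.31, and T and NK cells at -0.46.

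**Figure D4:**
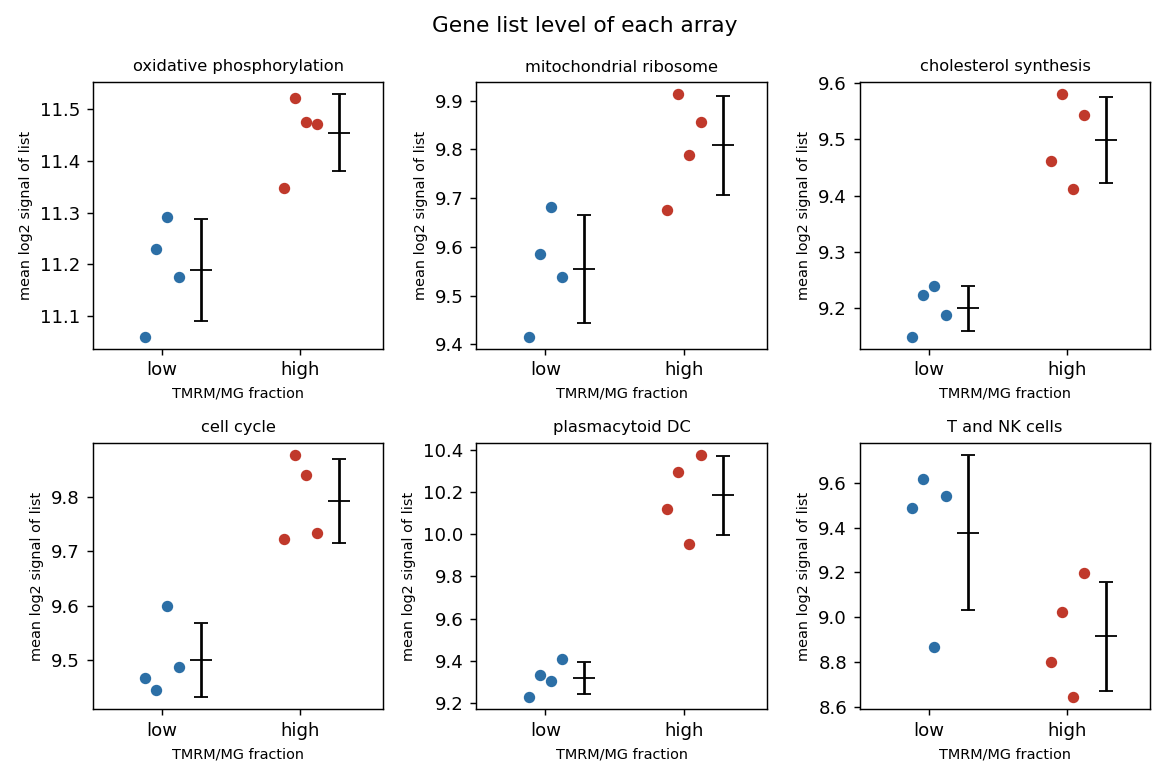
Mean log2 signal of 6 lists (y axis) on each array of the TMRM/MG-low and TMRM/MG-high fractions (points, with mean and SD at the side). The oxidative phosphorylation arrays average 11.5 in the high and 11.2 in the low fraction. For T and NK cells 1 low array lies among the high ones, and for the mitochondrial ribosome 1 low array lies just above 1 high array.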

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

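The test for T or NK cells mixed into the sort and the spike-in covariate were chosen after the results were seen. Singled out here are values of 1 array far from the other 3 of its group. There were 22 in 380 groups of 4 arrays, and chance gives about 1 in 20, or 19.

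Among genes, the array farthest from its group was high replicate 3 for Epha2 (8.91, others 9.68 to 9.76), Insig1 (9.53, others 9.68 to 9.71) and Tbx21 (7.33, others 7.80 to 7.86). It was high replicate 1 for Dld (9.74), Fis1 (11.39) and Batf3 (11.73, others 11.96 to 11.98), high replicate 2 for Rhobtb1 (8.80) and Jchain (11.68), and high replicate 4 for Cd3d (9.04) and Irf4 (9.93, others 9.19 to 9.29). In the low fraction it was replicate 1 for Ndufa9 (11.05) and Echs1 (9.77), replicate 2 for Mitf (8.01), replicate 3 for Tcirg1 (10.94, others 11.25 to 11.29) and Kif23 (10.06), and replicate 4 for Xcr1 (12.35) and Irf8 (12.41).

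Among list levels, mitochondrial biogenesis stood apart in high replicate 1 (8.87, others 9.02 to 9.04), B cells in low replicate 1 (9.94, others 9.68 to 9.71), and T and NK cells in low replicate 3 (8.87, others 9.49 to 9.62). Among controls, the poly-A spike-in lys (6.06, others 5.75 to 5.78) and the mean spike-in level (9.43, others 8.88 to 8.97) stood apart in high replicate 1.

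Mitochondrial genes were higher in TMRM/MG-high cells at the preset correlation (adjusted p = 0.41 with an estimated one). Their respiratory chain mean of 0.26 lay above all 10000 random lists matched on expression and gene length (percentile 100, highest 0.18). This makes such a trend less likely as the whole cause. The random genes were drawn singly, while the respiratory chain genes vary together (estimated correlation 0.51), so the spread of the random lists is too narrow to exclude it. The matched lists had a median of 0.10, against 0.0093 for all probe sets tested, so part of the shift goes with expression or length. Of the 35 splits of the arrays, only the real one gave a mean as large (0.26 against 0.24 for the highest other). With so few splits this makes chance less likely but cannot exclude it. The list did not pass after adjustment over the 37 sets (exact adjusted p = 0.0756). A labelling or RNA amount trend stays open: with the spike-in level as a covariate the difference was 0.043 (95% interval -0.29 to 0.38, against 0.11 to 0.42 without it), and the slope within groups was -0.24 (-0.56 to 0.089). The mean spike-in level separates the fractions without overlap (phe and lys alone, below the negative control median, do not). The hybridization controls, added to the labelled target, did so too (bioB -0.97, bioC -0.71, bioD -0.56 and cre -0.33). The arrays may therefore also have differed at the stage of the target or its hybridization. These signals are relative to the other probe sets after RMA, so the stage is not shown. How far such a difference between arrays moved the mitochondrial genes cannot be told apart from a difference in the cells, which was not tested.

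Plasmacytoid dendritic cell genes were higher in TMRM/MG-high cells at the preset correlation (adjusted p = 0.283 with an estimated one). With the spike-in level as a covariate the difference was 0.77 (95% interval 0.066 to 1.47), and the slope within groups was -0.11 (-0.79 to 0.58). The interval only just excludes 0. The covariate separates the fractions and averages the hybridization controls, added to the labelled target, with the poly-A ones. A labelling or RNA amount trend is thus less likely as the whole cause but cannot be excluded. Plasmacytoid cells mixed into the high fraction stay a candidate source, although Spib (0.19) and Cox6a2 (0.20) did not pass. Within groups the listed genes varied together (mean correlation 0.32, against a median of 0.032 and a 95th percentile of 0.19 for random lists matched on expression). Complex I (0.60) and cytosolic ribosome genes (0.47) did so more strongly, so this does not tell mixing from genes regulated together. A sort for cDC1 would remove such cells if complete, Siglech and Ly6c2 are also in the precursor list, and a cDC1 state with these genes was not tested.

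T and NK cell genes were lower in TMRM/MG-high cells at the preset correlation (adjusted p = 0.41 with an estimated one), but list levels per array did not separate the fractions (exact p = 0.0857, 95% interval of the difference -0.98 to 0.055). That exact test ignores the replicate numbers. Every low array lay above the high array of its number (camera adjusted p = 1.15e-09 with the replicate block), but whether the numbers pair the arrays is open. T or NK cells mixed into the low fraction stay a candidate source of the lower values. The T cell receptor complex genes Cd3e (-0.86), Cd3d (-0.82) and Cd3g (-0.76) fell, although Klrk1 (0.54) rose. Within groups the listed genes varied together (mean correlation 0.62, against a median of 0.0059 and a 95th percentile of 0.098 for matched random lists). Complex I genes did so nearly as much (0.60), so this does not tell mixing from genes regulated together. With the spike-in level as a covariate the difference was -0.14 (95% interval -1.57 to 1.30), too wide to decide on a labelling trend. A sort for cDC1 would remove such cells if complete, and a change within cDC1 was not tested.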

How the results depend on the processing

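The spike-in covariate was chosen after the data were seen, and the other alternatives before the data were examined. With the replicate block 1225 probe sets were higher and 650 lower, and the 17 set calls, the oxidative phosphorylation (0.26), cell cycle (0.29) and DC maturation (0.099) shifts kept their side of the threshold. Among named genes, Uqcrc1, Cox5a, Nrf1, Fis1, Slc25a4, Slc25a12, Cd83, Cxcl10, Ddx21, Dnajb9, Hsp90b1, Prdx1, Mitf and Fnbp1 passed it without the block and not with it. The numbers do not show that the arrays pair: 2 of 4 low and 1 of 4 high arrays correlated best with their own number, and the same-number mean of 0.095 was reached by 4 of the 24 pairings. Signal over background (area under the curve 0.918 and 0.912) and 4 arrays per group limit small differences.

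Counts moved with an intensity trend and robust fit (1950 higher), at 1.5-fold or more (202 and 145), at adjusted p under 0.1 (2061 and 1174), and in an unmoderated test with unequal variances (11 and 30), which does not pool the spread over probe sets. Leaving out 1 array gave 183 to 1680 higher and 218 to 793 lower. With an estimated correlation 0 sets were called, and oxidative phosphorylation (0.26) and cell cycle (0.29) lost their calls (adjusted p = 0.41 for each). Correlated genes count for less in that setting, but whether this alone removed the calls was not tested. Leaving out 1 array gave 0.22 to 0.30 for oxidative phosphorylation, 0.26 to 0.33 for the cell cycle, 0.071 to 0.15 for DC maturation (called without low replicate 2, adjusted p = 0.00595, and high replicate 3, 0.0379; 0.0124 to 0.549 over all alternatives but these) and 15 to 19 sets called.

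With the spike-in level as a covariate 0 probe sets were higher and 0 lower (limma; 472 and 568 at an unadjusted p under 0.05, lowest adjusted p = 0.727), and 10 sets were called at the preset correlation. Oxidative phosphorylation was 0.043 and cell cycle 0.090, not called, and DC maturation 0.21, called. The covariate separates the fractions, which widens intervals (the oxidative phosphorylation interval was 0.11 to 0.42 and became -0.29 to 0.38). Lists that turned were mitochondrial ribosome (-0.017), TCA cycle (-0.017), mitochondrial biogenesis (-0.059), NAD metabolism (-0.0090), cholesterol efflux (-0.30), MHC class II (-0.076), cytosolic ribosome (-0.052), lysosome (-0.035), apoptosis (-0.026), dye efflux pumps (-0.19), B cells (-0.012) and macrophages (-0.41). Genes that turned were Tex30 (-0.17), Atp5o (-0.089), Idh3a (-0.066), Slc25a12 (-0.047), Abca1 (-0.095), Rpl11 (-0.013), Mdm2 (-0.093), Abcb10 (-0.14), Abcc1 (-0.0047), Eif2s3y (0.25), Fcna (-0.49), Batf3 (-0.15), Sirpa (-0.12), Irf4 (-0.22), Opa1 (-0.0031), Tfam (-0.031), Abcb1a (-0.51) and Abcb1b (-0.073).

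Quantile normalization turned the integrated stress response (-0.0022) and B cells (-0.040), leaving out dim probe sets turned erythroid and platelet genes (0.025), and array weights turned interferon-stimulated genes (0.0063), cDC1 identity (0.020) and Eif2s3y (0.028). Results that turned without 1 array ranged over the 8 omissions from -0.033 to 0.036 for cDC1 identity, -0.15 to 0.020 for cDC2 identity, -0.059 to 0.080 for B cells, -0.039 to 0.053 for interferon-stimulated genes, -0.13 to 0.0078 for erythroid and platelet genes, -0.14 to 0.069 for Eif2s3y, -0.14 to 0.62 for Uty, -0.021 to 0.18 for Abcb1a and -0.031 to 0.24 for Irf4. Except where said, the cause was not tested. Of the 108 named genes called, 94 kept their call with the replicate block, 93 after quantile normalization, 47 in all 8 omissions and 0 with the spike-in covariate. Lost calls with the covariate do not mean smaller differences for every gene: Cd209d was 2.05 (1.83 without it), Klk1 1.55 (1.52), Epha2 1.63 (1.04), Atp1b1 1.20 (0.98), Leng8 -1.21 (-1.18) and Hnrnpm -1.14 (-1.04). Other genes shrank, such as Sccpdh to 0.015 (1.02 without it), Havcr1 to 0.84 (1.82) and Ppm1m to -0.51 (-1.06). All these examples were chosen after their values were seen.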

Other observations

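The test of same-numbered arrays was chosen after the result was seen. Because Leng8, Rsrp1 and Hnrnpm were among the largest falls, the hypothesis was that genes of SR proteins and CLK kinases, which regulate splicing, are lower as a class. It was not borne out: 22 of 24 listed genes were measured, 1 rose (Srsf9, 0.34) and 3 fell (Luc7l3, -0.64, Clk2, -0.50, and Acin1, -0.47), the mean was -0.040 with a median of 0.032, and camera gave p = 0.244 (p = 0.527 with an estimated correlation).

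Of the 35 splits of the 8 arrays into 4 and 4, the real one included, 1 gave as many calls as the real 1831 (0 for the highest other; 5653 against 4724 at an unadjusted limma p under 0.05), and 1 gave a cell cycle shift as large (0.29, highest other 0.23), the fewest possible. With so few splits this makes chance less likely for the calls and for the cell cycle list, but cannot exclude it. The cell cycle list did not pass after adjustment over the 37 sets (exact adjusted p = 0.0756). For DC maturation 6 splits gave a shift as large (0.099, highest other 0.16). For the number of sets called 9 did (17, highest other 23). The real split does not stand apart from the others in these.

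The NK cell genes Ncr1 (8.84 and 8.50) and Eomes (8.28 and 7.68) were lowest in replicate 3 of both fractions. The Y-linked genes Kdm5d and Uty were lowest in replicate 4 of both, but lay below the negative control median there and carry no weight. Same-numbered arrays may come from the same animals. Over all probe sets, 4 of the 24 pairings of the numbers, the real one included, gave a mean correlation of deviations as high as the 0.095 of the same numbers, which leaves this open.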
